A study of Mus musculus with 4 samples.

How the data were processed

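The series holds 4 RNA-seq libraries of mouse pachytene spermatocytes sorted after ex vivo treatment of testicular cell suspensions, 2 from BMH21-treated and 2 from mock-treated suspensions, called biological replicates in the labels. RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit, per the labels' protocols. Fastp, STAR, SAMtools, featureCounts and DESeq2 and the genome build mm10 are named per the submitters' processing notes, with no versions, order or settings. Whether the counting used strand, and how it treated reads that map to several genes, is not given in the sources used here, so the values of overlapping, antisense and near-identical genes are uncertain. Exon overlaps were taken from GENCODE M21 for the X- and Y-linked genes and for every gene named in the results.

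The authors deposited 1 table of 15733 protein-coding genes, each with a total of at least 4 counts over the libraries. It gives raw read counts per gene and library, which the authors deposited without normalization and from which the present tests start. The size-factor-normalized values in the table (signal) were made by the authors by dividing each library's counts by 1 size factor; they entered no test. The authors' log2 fold changes with their standard errors, the authors' Wald score and the authors' p-values, raw and Benjamini-Hochberg adjusted over the table, are DESeq2 output, per the submitters' processing notes and the file headers; DESeq2 run on the counts gave log2 fold changes within 2.83e-05 of them. The gene positions in the table differ from those of the GENCODE M21 annotation of GRCm38 (mm10) for all but 369 of 15670 genes matched by gene identifier, although the notes name mm10, while the chromosome was the same for all 15670. Coordinates are therefore those of GENCODE M21 on GRCm38, 1-based, taken by gene identifier, and the positions in the table were not used.

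Differential expression was tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with its minimum count of 10, counts were scaled by TMM factors, and the quasi-likelihood test was fitted with group alone. The filter kept 13793 genes and removed 1940, of which 89 were X-linked, 28 Y-linked and 1823 autosomal. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes. The common biological coefficient of variation was 4.09%, and 5176 genes had an unadjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. This is an approximation. For large rises from few mock counts, as in many X- and Y-linked genes, it is too small and can lie below counting error. Expression is given in counts scaled to CPM with TMM-scaled library sizes, as mean and SD over 2 replicates. Shares of counts per chromosome carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Libraries held 30964370 to 41548269 counts over the listed genes. With 2 replicates per group the p-values rest on a spread pooled across genes.

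The comparison, its test, 30 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule took the 10 genes higher and 10 lower with the smallest p among called genes with a log2 fold change of at least 1 in size, a mean of at least 10 CPM and no overlap between groups, leaving out predicted or unnamed models. It also took up to 4 called members with the smallest p from each list with at least 3 called members or a camera call, Polr1a, Cdkn1a and Mdm2 in any case, and the 2 most abundant members of each marker list. Only 9 lower genes passed. Genes named outside this rule were chosen after their values were seen. The results say so for most of them, and it holds also for Dmc1, Foxo4, Pdha2, Pgk2, Prdm9 and Snhg4. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were tested, which held for 28 of the 30. Of these 28, 2 were called, the single-copy X-linked and the Y-linked list, and 0 with an estimated correlation; on autosomal genes alone, a test added after the data were seen, 25 were tested, 2 were called (ribosomal proteins and the stress response) and 0 with an estimated correlation. For each list, calls were also counted with p adjusted over the list alone.

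The count test and camera were tested on simulated counts for 13558 genes with the means and library sizes of the real libraries. For the comparison of BMH21 with mock, 23 of 50 genes changed by 1.25-fold were recovered, 35 of 50 at 1.5-fold, 45 of 50 at 2-fold and 49 of 50 at 4-fold, with 10 false calls among 162. The changed genes were drawn only from those with a mean of at least 1 CPM, so recovery of weaker genes was not measured. In 1 simulated data set, camera called a list shifted by 0.3 on the log2 scale with the preset correlation, and 0 lists with an estimated correlation. The latter thus missed a shift of this size, and its power at other sizes was not measured. Genes were simulated independently of each other, and far fewer were changed than were called in the real data, so recovery there may differ.

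Near-identical copies were searched with blastn 2.17.0 among protein-coding transcripts of GENCODE M21 for 15551 genes, and a copy was counted at 95% identity over at least 50% of the transcript. Alternatives were RLE size factors, upper quartile scaling, DESeq2 1.42.0 (run on all 15733 genes without the filter), no filter, a stricter filter (at least 1 CPM in all 4 libraries or a mean of at least 5 CPM), a block for the replicate number, leaving out each library, a fold change of at least 2, an adjusted p under 0.01, X-linked genes with a mean of at least 5 CPM, and an estimated correlation for camera. TMM factors from autosomal genes alone and DESeq2 on the 13793 genes that passed the filter were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes outside the deposited table, ribosomal RNA among them, were not analysed here.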

Results

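The mRNA of mouse pachytene spermatocytes was sequenced with and without BMH21, a small molecule that intercalates into DNA and is known as an inhibitor of RNA polymerase I, the enzyme that transcribes ribosomal RNA genes. Suspensions of single testicular cells were kept for 12 h ex vivo with 2.5 µM BMH21 or with the solvent DMSO (mock), and pachytene cells were then sorted by flow cytometry on the DNA dye Hoechst. Pachytene is the stage of male meiosis at which homologous autosomes are synapsed and at which the X and Y chromosomes, largely unsynapsed, are transcriptionally silenced (meiotic sex chromosome inactivation). There were 4 libraries, 2 biological replicates of each condition. Over the listed protein-coding genes the libraries held 41548269 and 30964370 counts (mock replicates 1 and 2) and 33338160 and 37555727 counts (BMH21 replicates 1 and 2). Between 15398 and 15535 genes had counts in a library. The replicates of each group differed by more than sampling noise (chi-square per degree of freedom 3.21 in mock and 3.76 in BMH21), which argues against 1 library sequenced again. That they are biological replicates rests on the labels, and each library was counted as its own replicate.

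The comparison of BMH21 with mock asked which mRNAs differed in pachytene cells after the inhibitor. Transcripts of both sex chromosomes rose relative to those of the autosomes. The scaling rests mostly on autosomal genes and centres them near no change, so a change shared by all of them could not be seen. X-linked genes took 0.0401% ± 0.00048 of the counts in mock and 0.883% ± 0.0073 in BMH21 (SD, n = 2 each), a 22.0-fold difference. Y-linked genes went from 0.00136% ± 2.7e-05 to 0.0410% ± 0.00049 (SD, n = 2 each), a 30.2-fold difference. Per library the X share was 0.0398% (95% exact binomial interval 0.0392 to 0.0404) and 0.0405% (0.0398 to 0.0412) in mock, and 0.878% (0.874 to 0.881) and 0.888% (0.885 to 0.891) in BMH21, with intervals that cover counting error only. Mitochondrial mRNAs took 0.344% ± 0.0019 of the counts in mock and 0.337% ± 0.0059 in BMH21 (SD, n = 2 each).

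Of 343 X-linked genes tested, 251 (73.2%) rose, 245 of them at least 2-fold, and 1 fell (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of 10 Y-linked genes tested, 9 rose and 0 fell; at an unadjusted p under 0.05 edgeR gave 9 higher and 0 lower, as did DESeq2 at its adjusted p. The median log2 fold change was 4.19 over X-linked genes (quartiles 0.96 and 5.70) and 6.30 over Y-linked genes, against -0.01 over 13427 autosomal genes (quartiles -0.18 and 0.16). The difference of the medians was 4.19 for X, which is 18.3-fold, and 6.30 for Y. In the camera test against all other genes, p was 2.42e-239 for X and 5.34e-63 for Y with the preset correlation, and 0.00799 and 0.00689 with an estimated correlation. The filters counted the BMH21 libraries too, so X-linked genes low in mock passed more readily if they rose. The size of the X difference therefore depended on which genes were kept, and filtered values are raised by this selection. Over all 432 listed X-linked genes it was 2.76 in edgeR and 2.92 in DESeq2, with a stricter filter it was 5.31, and over genes with a mean of at least 5 CPM (library-size-scaled counts) 5.82. DESeq2 on the 343 genes that passed the filter, a fit added after the data were seen, gave 4.22. With 0.5 CPM added to each value before the log, the X difference between a BMH21 and a mock library was 2.21 to 2.34. Its size therefore also depended on how counts near 0 in mock were handled. The share of X-linked genes called higher was 57.9% of 432 without a filter and 84.5% of 142 with the stricter one, a share raised by the same selection. Of 38 listed Y-linked genes 10 passed the filter, and without a filter 9 were called higher. The Y median and share above cover only the genes that passed, and the same selection applies to them.

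**Figure D1:**
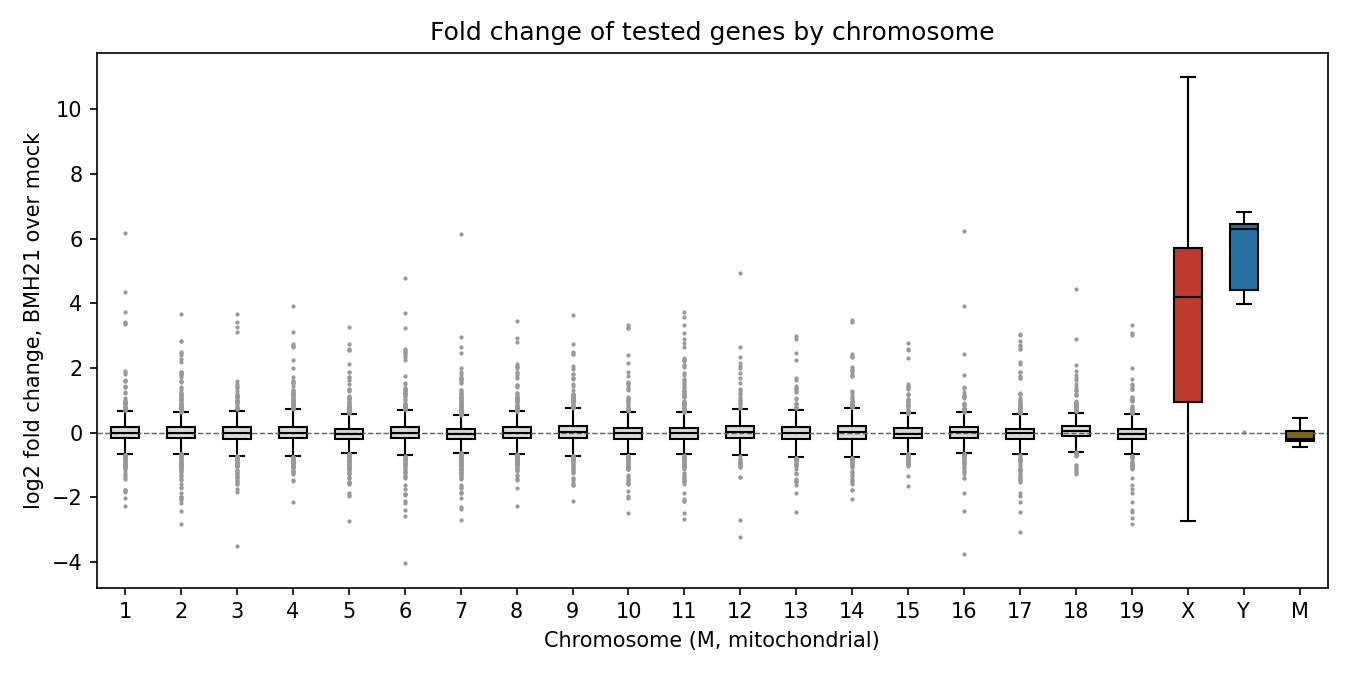
Log2 fold change (BMH21 over mock, vertical axis) of the tested genes of each chromosome (horizontal axis; M, mitochondrial); boxes span the quartiles, lines mark medians, whiskers reach 1.5 times the interquartile range and points lie beyond. The autosomal medians lie between -0.03 and 0.05, that of X at 4.19 and that of Y at 6.30.

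Among the X-linked genes with the smallest p were Fmr1, which encodes an RNA-binding translational regulator, Usp9x, a deubiquitinase, Hcfc1, a transcriptional coregulator, Alg13, an enzyme of protein glycosylation, and Scml2, a germline Polycomb protein. Fmr1 (ENSMUSG00000000838.18, chromosome X, 68678541 to 68717963 on GRCm38) rose from 1.97 ± 0.250 to 264 ± 1.05 CPM (SD, n = 2 each), a log2 fold change of 7.05 ± 0.07 (SE) with an edgeR adjusted p of 8.34e-68. An annotated predicted gene, Gm27838, overlaps its exons on the same strand. Leaving out 1 library gave Fmr1 a log2 fold change of 6.94 to 7.20. For rises of this size the SE given here is too small. Cfap47 (ENSMUSG00000073077.8, chromosome X, 79266559 to 79517285), which encodes a protein of cilia and flagella, rose from 3.88 ± 0.144 to 316 ± 3.57 CPM (SD, n = 2 each), with a log2 fold change of 6.34 ± 0.06 (SE) and an edgeR adjusted p of 5.15e-69. Dcaf8l (ENSMUSG00000035395.12, chromosome X, 89403848 to 89409689) rose from 3.24 ± 0.238 to 308 ± 4.04 CPM (SD, n = 2 each), by 6.56 ± 0.06 (SE) on the log2 scale. The remaining genes that the naming rule took from X were Alg13 (chromosome X, 144317804 to 144374450; 7.59 to 369 CPM, log2 fold change 5.63), Zfp711 (chromosome X, 112600526 to 112635070; 6.09), Xk (chromosome X, 9272756 to 9313250; 6.94), Usp9x (chromosome X, 13071498 to 13173328; 8.75 to 275 CPM, 4.99), Pwwp3b (chromosome X, 139210042 to 139238335; 6.16), Hcfc1 (chromosome X, 73942792 to 73966357; 6.02) and Scml2 (chromosome X, 161117193 to 161258213; 1.99 to 171 CPM, 6.45). All 10 of these were X-linked, out of 126 genes that passed the rule for higher genes.

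The list of ubiquitously expressed single-copy X-linked genes moved with the chromosome. Of 38 members tested, 33 rose and 0 fell over all genes, and 35 and 0 adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 35 higher and 0 lower, and DESeq2 gave 30 and 0. The median log2 fold change was 4.51, which is 22.8-fold; camera gave an adjusted p of 1.18e-150, and an adjusted p of 0.117 with an estimated correlation. Zfx, a zinc-finger transcription factor (chromosome X, 94074631 to 94123702), rose from 1.10 to 149.8 CPM (log2 fold change 7.09 ± 0.09 (SE)), with an annotated antisense gene, Gm14798, over part of its exons. The 5 members that did not pass the test, named after their values were seen, were Stag2 (2.25 to 3.31 CPM, log2 fold change 0.55), the glycolytic gene Pgk1 (0.917 to 1.37 CPM, 0.57), Emd (0.90), Flna (0.21) and Utp14a (1.30; called with RLE size factors, 1.30, and without a filter, 1.30).

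All 7 tested members of the Y-linked list rose, over all genes and adjusted over the list alone, and 0 fell; edgeR at an unadjusted p under 0.05 and DESeq2 each also gave 7 and 0. Their median log2 fold change was 6.28; camera gave an adjusted p of 3.93e-73, and an adjusted p of 0.117 with an estimated correlation. Zfy2 (chromosome Y, 2106015 to 2170409) and Zfy1 (chromosome Y, 725128 to 797409), zinc-finger genes that encode drivers of spermatocyte death when expressed at pachytene, rose from 1.43 to 126 CPM (log2 fold change 6.45 ± 0.09 (SE)) and from 0.857 to 68.8 CPM (6.32 ± 0.13 (SE)); they are near-identical in sequence, so the division of reads between them is uncertain. Usp9y (chromosome Y, 1298961 to 1459782) rose from 2.20 to 104 CPM (5.57 ± 0.09 (SE)), and Eif2s3y (chromosome Y, 1010543 to 1028847), which encodes a translation initiation factor subunit needed for spermatogonial proliferation, from 4.02 to 64.1 CPM (3.98 ± 0.10 (SE)). The 1 Y-linked gene tested that was not called, Gm21095, had a log2 fold change of 0.01 and belongs to a family of near-identical copies; it was singled out after its value was seen.

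**Figure D2:**
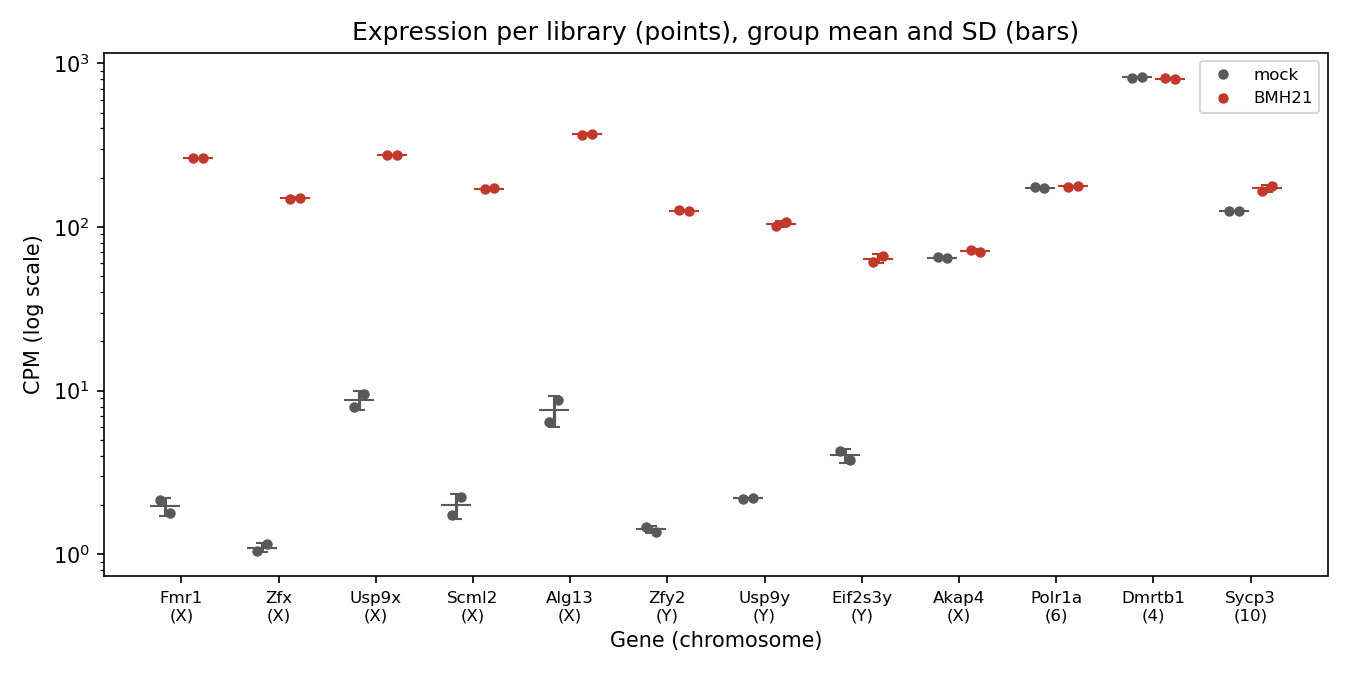
Expression (CPM, vertical log axis) of 12 genes in each library (points), with the group mean and SD (bars, n = 2), for mock (grey) and BMH21 (red). The X-linked Fmr1 goes from 1.97 to 264 CPM and the Y-linked Zfy2 from 1.43 to 126 CPM, while Akap4 on X reads 64.9 and 71.2 CPM and the autosomal Polr1a 174 and 177 CPM.

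The rise was spread along the X chromosome. In windows of 20 Mb, between 64.3% and 89.2% of the tested genes were called higher, and the window medians of the log2 fold change ran from 2.56 (80 to 100 Mb) to 4.47. The 251 X-linked genes called higher had a median of 0.311 CPM in mock and 7.79 CPM in BMH21. The remaining 92 had medians of 0.619 and 0.708 CPM. Among these was Akap4 (chromosome X, 7067519 to 7078609), which encodes a scaffold protein of the sperm fibrous sheath, at 64.9 ± 0.414 CPM in mock and 71.2 ± 1.67 CPM in BMH21 (SD, n = 2 each; edgeR adjusted p = 0.0589). Akap4 is also a member of the spermatid marker list, so its counts may not come from pachytene cells alone, which was not tested. Cylc1, a gene for a sperm head cytoskeleton protein, was at 3.06 and 3.63 CPM, and Cypt1 at 2.45 and 2.92 CPM. Akap4, Cylc1 and Cypt1 were singled out after their values were seen. The 1 X-linked gene that fell was Foxo4, a forkhead transcription factor, from 0.598 to 0.0906 CPM (log2 fold change -2.74 ± 0.87 (SE), edgeR adjusted p = 0.0113); DESeq2 called 0 X-linked genes lower, and edgeR called 1 lower at an unadjusted p under 0.05. Foxo4 lost its call without mock replicate 1 (-2.67), mock replicate 2 (-2.78) or BMH21 replicate 2 (-1.71), and read -7.47 without BMH21 replicate 1.

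**Figure D3:**
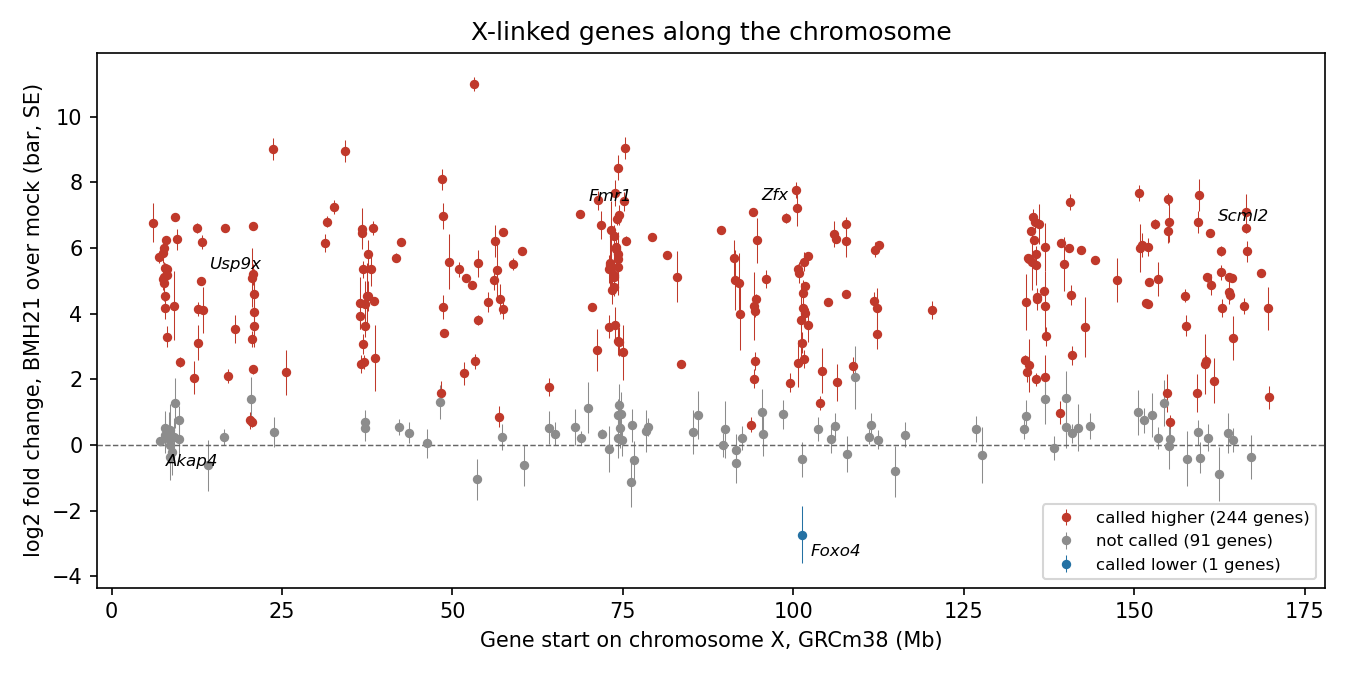
Log2 fold change (BMH21 over mock, vertical axis; bars, SE) of X-linked genes by gene start in Mb on GRCm38 (horizontal axis), coloured by the edgeR call, for the genes with GRCm38 coordinates (244 called higher). Genes called higher lie along the length of the chromosome, interspersed with genes that were not called, Akap4 among them, and 1 gene called lower, Foxo4. The SE is an approximation, and the bars of genes that rose strongly are too short.

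Genes close to 0 in the mock libraries were compared across chromosomes with no filter on counts. Of 3942 autosomal genes under 1 CPM in mock, 147 (3.73%) were called higher, and their median log2 fold change was 0.02 (quartiles -0.65 and 0.62). Of 332 such X-linked genes, 179 (53.9%) were called higher, with a median of 2.65.

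On the autosomes genes changed in both directions. Of 13427 tested, 2021 rose (15.1%) and 1725 fell (12.8%), the median size of a called log2 change was 0.32, 307 genes at least doubled and 150 at least halved. These larger called changes lay mostly in weakly expressed genes, where small changes could hardly pass the test, so the counts do not show that such genes changed more. Under a mean of 1 CPM all 74 higher and 52 lower calls were at least 2-fold, from 1 to 10 CPM 188 of 374 and 89 of 377, from 10 to 100 CPM 44 of 953 and 9 of 824, and above that 1 of 620 and 0 of 472. Over all chromosomes 4013 genes were called, 2282 higher and 1731 lower (56.9% higher). Under upper quartile scaling the split was 1805 higher and 2480 lower (42.1% higher), and on the autosomes 1546 and 2473 (38.5% higher, against 54.0%); this scaling shifted the log2 fold changes by a median of -0.05.

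The autosomal genes that fell by at least 2-fold with the smallest p were Zfp820, a zinc-finger gene, and Txlna, which encodes a syntaxin-binding protein. Zfp820 (ENSMUSG00000069743.6, chromosome 17, 21816885 to 21845772) went from 33.0 ± 0.771 to 11.9 ± 0.116 CPM (SD, n = 2 each; log2 fold change -1.47 ± 0.10 (SE), edgeR adjusted p = 6.09e-21), and Txlna (chromosome 4, 129626078 to 129641065) from 40.8 to 20.2 CPM (-1.02 ± 0.08 (SE)). The other genes that passed the rule, 9 in all, were the spectrin gene Sptbn1 (-1.27), Rhobtb2 (-1.25), Abitram (-1.21), the integrin gene Itga4 (-1.15), the transcription factor genes Sox8 (-1.15) and Trp63 (-1.13), and Edem3 (13.6 to 6.78 CPM). Sptbn1, Sox8 and Itga4 overlap annotated antisense genes, and the strand setting of the counting is not given in the sources used here.

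Because the rule took only X-linked genes on the higher side, the same rule was applied to autosomal genes after the data were seen, and 45 passed. The first was Dazl, which encodes a germ-cell RNA-binding protein (ENSMUSG00000010592.10, chromosome 17, 50279395 to 50293636); it rose from 67.6 ± 1.30 to 154 ± 9.41 CPM (SD, n = 2 each; log2 fold change 1.19 ± 0.05 (SE), edgeR adjusted p = 5.01e-33). Fam53c rose by 1.30, Trim52 by 2.02, the phosphatase gene Phlpp2 by 2.08, Dnm1l, which encodes the GTPase of mitochondrial fission, by 1.09 and Map7d1 by 1.54 on the log2 scale. Zfp354c (2.25), Malt1 (2.10), Epm2aip1 (1.18) and the cytokine receptor gene Il6st (1.30) completed the 10.

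The RNA polymerase I machinery itself moved little at the mRNA level. Polr1a, the gene of the catalytic subunit (ENSMUSG00000049553.12, chromosome 6, 71909053 to 71984935), was at 174 ± 0.510 CPM in mock and 177 ± 1.93 CPM in BMH21 (SD, n = 2 each), a log2 fold change of 0.02 ± 0.04 (SE) with an edgeR adjusted p of 0.705; the value was -0.02 under upper quartile scaling. Of 15 tested members of the polymerase I list, 1 rose (Rrn3, 0.30) and 1 fell (Polr1h, -0.48), both named after their values were seen; Rrn3 lost its call under upper quartile scaling (0.25), in DESeq2 (0.30) and with any 1 library left out (0.27 to 0.33), and Polr1h in DESeq2 (-0.48), with the replicate number as a block (-0.48) and without mock replicate 1 (-0.34) or BMH21 replicate 1 (-0.43). Adjusted over the list alone the counts were 0 and 0, by DESeq2 0 and 0, and at an unadjusted p under 0.05 in edgeR 2 and 2. Nucleolar ribosome assembly factors went both ways. Of 52 tested, 12 rose and 6 fell (16 and 6 adjusted over the list alone). Mybbp1a, a nucleolar Myb-binding protein gene, rose from 37.6 to 68.5 CPM (log2 fold change 0.86), Utp20 by 0.45, the nucleophosmin gene Npm1 by 0.23 and Gnl3 by 0.82.

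Of 76 cytosolic ribosomal protein mRNAs tested, 35 rose, 0 fell and 41 were not called, 34 of the 35 being autosomal; adjusted over the list alone 39 rose and 0 fell, at an unadjusted p under 0.05 edgeR gave 44 and 0, and DESeq2 gave 22 and 0. Rps23 (0.24), Rpl7 (0.20) and Rpl37 (0.26) rose, as did the X-linked Rpl10 (0.311 to 2.91 CPM, 3.16), whose sequence has a near-identical copy and whose value was 3.90 without mock replicate 1. The median log2 fold change was 0.12. Camera gave an adjusted p of 0.492 over all genes; over autosomal genes alone, a test added after the data were seen, it gave an adjusted p of 6.70e-04, and an adjusted p of 0.778 with an estimated correlation. Under upper quartile scaling 16 rose and 1 fell. The list of non-coding snoRNA host genes had 1 tested member, Snhg4, which rose by 0.19 (1 higher also adjusted over the list alone). The model tested under this name is listed as protein-coding and overlaps exons of Matr3, so its value cannot be read as that of a non-coding host transcript.

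Targets of p53 were split between higher and lower. Of 22 tested, 5 rose and 4 fell (5 and 5 adjusted over the list alone), and 4 rose and 5 fell under upper quartile scaling. The pro-apoptotic gene Pmaip1 (chromosome 18, 66458533 to 66465565) rose from 5.48 to 17.8 CPM (log2 fold change 1.69 ± 0.13 (SE)), Ei24 by 0.66 and Trp53inp1 by 0.54, and Ckap2 fell from 31.2 to 20.1 CPM (-0.63). Perp also rose (3.34), and Sesn1 (-0.22), Plk2 (-0.50) and Pidd1 (-0.65) fell; these 4 were named after their values were seen. Perp read 7.28 without mock replicate 1, which leaves only a mock library at 0 CPM, and lost its call without mock replicate 2 (2.54); Sesn1 lost its call in DESeq2 (-0.23) and without mock replicate 1 (-0.20) or BMH21 replicate 1 (-0.12), and Plk2 in DESeq2 (-0.50) and with any 1 library left out (-0.54 to -0.47). Mdm2, which encodes the ubiquitin ligase of p53, rose from 306 to 329.8 CPM (0.11, edgeR adjusted p = 0.00282), but lost its call under upper quartile scaling (0.06, adjusted p = 0.113) and without mock replicate 2 (0.10, adjusted p = 0.0759). The cell cycle inhibitor gene Cdkn1a was at 0.216 ± 0.103 CPM in mock and 0.276 ± 0.123 CPM in BMH21 (SD, n = 2 each; adjusted p = 0.803).

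Of 18 tested core apoptosis genes, 5 rose and 2 fell (6 and 3 adjusted over the list alone). The caspase gene Casp2 rose from 4.43 to 10.2 CPM (log2 fold change 1.20), the somatic cytochrome c gene Cycs by 2.25, Bcl2l1 by 0.23 and Birc2 by 0.21. Casp9 rose (0.38) and Birc5 (-0.16) and Ripk1 (-0.20) fell, named after their values were seen; Birc5 lost its call without mock replicate 2 (-0.15) or BMH21 replicate 1 (-0.14), and Ripk1 in DESeq2 (-0.20) and without mock replicate 1 (-0.15), BMH21 replicate 1 (-0.17) or BMH21 replicate 2 (-0.23).

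Of 18 tested genes of the unfolded protein and integrated stress response, 9 rose, 2 fell and 7 were not called (10 and 2 adjusted over the list alone), with a median log2 fold change of 0.15. The endoplasmic reticulum chaperone genes Pdia4 (20.5 to 37.3 CPM, 0.86), Hspa5 (0.16) and Dnajb9 (0.26) rose, as did Sel1l, a gene of protein degradation at that organelle (0.28). Herpud1 (-0.38) and the serine synthesis gene Psat1 (-1.04) fell, named after their values were seen; Psat1 lost its call without mock replicate 1 (-0.84) or BMH21 replicate 2 (-0.84). Camera gave an adjusted p of 0.668 over all genes; over autosomal genes alone, added after the data were seen, it gave an adjusted p of 0.0113, and an adjusted p of 0.869 with an estimated correlation.

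Of 18 heat shock and chaperone genes, 4 rose and 3 fell (6 and 3 adjusted over the list alone). Hsp90ab1 (0.37), Hspa8 (0.47), Hspd1 (0.87) and Hsf1 (0.26) rose, and Hspa2 (-0.07), Hsp90aa1 (-0.04) and Hsf2 (-0.31) fell; Hspd1, Hsp90aa1 and Hsf2 were named after their values were seen. Hsf1 lost its call without mock replicate 2 (0.18), and Hspa2 without mock replicate 1 (-0.07) and without mock replicate 2 (-0.06). Hsf2 lost its call in DESeq2 (-0.31), with the replicate number as a block (-0.31) and with any 1 library left out (-0.35 to -0.27), Hsp90aa1 in DESeq2 (-0.04), without a filter (-0.04), with autosomal TMM factors (-0.04) and without mock replicate 1 (-0.04), mock replicate 2 (-0.04) or BMH21 replicate 1 (-0.02), and Hspd1 in DESeq2 (0.86) and without mock replicate 1 (0.72) or BMH21 replicate 2 (0.65). Of 13 immediate-early genes, 2 rose, Btg1 (0.25) and Zfp36 (2.97), and 1 fell, Jun (-0.48), with the same counts adjusted over the list alone. Zfp36 lost its call in DESeq2 (3.13), without mock replicate 2 (2.14) and without BMH21 replicate 1 (2.40), and read 7.86 without mock replicate 1, which leaves only a mock library at 0 CPM, so the size of its change is poorly determined. Jun lost its call without BMH21 replicate 1 (-0.41). Of 9 interferon and NF-kB response genes 0 were called in edgeR, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 in DESeq2.

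Of 21 genes of the synaptonemal complex, chromosome axis and meiotic cohesin, 6 rose and 5 fell (6 and 5 adjusted over the list alone). Sycp3, which encodes a protein of the lateral element, rose from 125 to 172 CPM (0.46 ± 0.04 (SE)), Hormad1 by 0.33, the cohesin gene Smc1b by 0.29 and Sycp1 by 0.27. Sycp2 (-0.13), Rec8 (-0.51), Terb1 (-0.22), Terb2 (-0.43) and Kash5 (-0.16) fell, named after their values were seen. Calls were lost for Rec8 in DESeq2 (-0.52) and without mock replicate 2 (-0.44) or BMH21 replicate 1 (-0.27), for Terb2 without BMH21 replicate 1 (-0.23) and for Kash5 without mock replicate 2 (-0.11) or BMH21 replicate 2 (-0.10). The median of the list was 0.01, and -0.04 under upper quartile scaling.

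Of 35 meiotic recombination genes, 5 rose and 6 fell (5 and 6 adjusted over the list alone). The counts were 5 and 10 under upper quartile scaling and 5 and 3 in DESeq2. The X-linked Tex11 rose from 0.191 to 7.42 CPM (5.25), Msh4 by 0.72 and Iho1 by 0.47; Hfm1 (0.20, named after its value was seen) and Spata22 (0.49) also rose, the former without a call when mock replicate 2 was left out (0.16) and the latter when BMH21 replicate 2 was left out (0.34). Of 30 DNA damage response and sex chromosome silencing factors, 4 rose and 6 fell (4 and 6 adjusted over the list alone). Scml2, itself X-linked, rose by 6.45, Topbp1, which encodes an activator of the ATR kinase, from 56.9 to 87.8 CPM (0.62), and Rnf8 (0.28) and Rad17 (0.35) also rose, these last named after their values were seen; Rnf8 lost its call in DESeq2 (0.27) and without mock replicate 1 (0.15) or BMH21 replicate 1 (0.27). Atf7ip, a partner of the histone methyltransferase SETDB1, fell from 144 to 106 CPM (-0.44), and Mdc1, which encodes the mediator that spreads DNA damage signalling over the sex chromosomes, from 653 to 582 CPM (-0.17).

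Of 23 piRNA pathway and germ granule genes, 8 rose and 5 fell (8 and 6 adjusted over the list alone). Piwil2 (0.30), Rnf17 (0.27) and Tdrd5 (0.17) rose, and Piwil1, which encodes the PIWI protein that binds pachytene piRNAs, fell (-0.16). Mybl1 (-0.11), Tdrd6 (-0.05), Tdrd9 (-0.09) and Mov10l1 (-0.13) fell, named after their values were seen. Calls were lost for Mybl1 in DESeq2 (-0.11) and without mock replicate 1 (-0.10), mock replicate 2 (-0.11) or BMH21 replicate 1 (-0.07), for Tdrd6 without mock replicate 1 (-0.05) or mock replicate 2 (-0.05), for Tdrd9 without mock replicate 1 (-0.05) and for Mov10l1 without mock replicate 1 (-0.14), mock replicate 2 (-0.12) or BMH21 replicate 1 (-0.11). Under upper quartile scaling 5 rose and 7 fell, and the median went from 0.03 to -0.01. Of 30 pachytene-enriched genes, 8 rose and 7 fell (8 and 7 adjusted over the list alone), with Mllt10 (0.21) and Cks2 (0.39) higher and Tesmin (-0.21) lower; under upper quartile scaling 4 rose and 12 fell. Of 32 genes of the G2 to meiotic division transition, 6 rose and 10 fell (6 and 11 adjusted over the list alone). The X-linked cyclin gene Ccnb3 rose from 0.526 to 27.5 CPM (5.71), the spindle checkpoint gene Mad2l1 by 0.91 and Cdk2 by 0.21, and the separase gene Espl1 fell (-0.28).

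Autosomal retrogenes of X-linked genes, copies that are expressed while X is silent, had a median log2 fold change of 0.02. Of 9 tested, 2 rose, Cetn1 (0.19) and Rbmxl1 (0.27), both named after their values were seen, and 0 fell, with the same counts adjusted over the list alone. Rbmxl1, which has a near-identical copy, lost its call in DESeq2 (0.27) and with any 1 library left out (0.25 to 0.28). At an unadjusted p under 0.05 edgeR gave 2 higher and 1 lower, DESeq2 gave 1 and 0, and upper quartile scaling 2 and 1. Pgk2, the retrogene of Pgk1, was at 364 ± 3.10 CPM in mock and 371 ± 0.965 CPM in BMH21 (SD, n = 2 each), and Pdha2 at 195 and 198 CPM.

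Of 28 RNA polymerase II, topoisomerase and elongation genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone), and 6 rose and 4 fell under upper quartile scaling. The topoisomerase gene Top2b rose from 2.45 to 9.45 CPM (1.97), the elongation factor gene Ell2 by 1.26 and Top1 by 0.16, while Polr2a, the gene of the largest polymerase II subunit, fell from 234 to 196 CPM (-0.26); Supt5 fell too (-0.10, named after its value was seen), but not without mock replicate 2 (-0.07). Of 35 spliceosome and SR protein genes, 12 rose and 8 fell (14 and 9 adjusted over the list alone), among them Tra2b (0.43) and Srsf10 (0.43) higher and Srsf6 (-0.54) and Snrnp70 (-0.30) lower; upper quartile scaling gave 8 and 9. Of 15 germline histone variants and linker histones, 1 rose (H3f3b, 0.19) and 1 fell (H2az1, -0.23), both named after their values were seen, with the same counts adjusted over the list alone. Of 13 mitochondrially encoded mRNAs, 1 rose, mt-Co1 (0.07), and 5 fell, mt-Cytb (-0.26), mt-Nd5 (-0.23), mt-Nd6 (-0.30), mt-Nd4 (-0.19) and mt-Nd2 (-0.18), with the same counts adjusted over the list alone; mt-Co1 and mt-Nd2 were named after their values were seen, and mt-Nd2 lost its call in DESeq2 (-0.19) and without mock replicate 2 (-0.05) or BMH21 replicate 1 (-0.17), and mt-Co1 under upper quartile scaling (0.02). Upper quartile scaling gave 0 higher and 6 lower.

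Markers of other cell types showed no common shift. Of 11 spermatogonial markers, 2 rose, Sohlh2 (0.582 to 5.62 CPM, 3.28) and the X-linked Rhox13 (5.36), and 2 fell, Kit (-0.58) and Zbtb16 (-0.95), with the same counts adjusted over the list alone. Kit lost its call in DESeq2 (-0.58), with the replicate number as a block (-0.58) and without mock replicate 1 (-0.64), mock replicate 2 (-0.51), BMH21 replicate 1 (-0.55) or BMH21 replicate 2 (-0.61); Zbtb16 lost its call without mock replicate 2 (-0.74) and without BMH21 replicate 1 (-0.77). Rhox13 read 9.88 without mock replicate 1, which leaves only a mock library at 0 CPM, and 4.57 without mock replicate 2. The most abundant of these markers, Id4 and Gfra1, were at 38.4 and 8.54 CPM in mock and 35.2 and 8.29 CPM in BMH21. Of 13 markers of leptotene and zygotene cells, 3 rose, the X-linked Esx1 (3.31) and Rhox13 and the autosomal Sycp1, and 2 fell, Dmrtc2 (-0.32) and Meiob (-0.63, named after its value was seen); 4 rose and 2 fell adjusted over the list alone. Meiob lost its call in DESeq2 (-0.64) and without mock replicate 2 (-0.45) or BMH21 replicate 1 (-0.30). Dmc1 was at 0.383 ± 0.00188 CPM in mock and 0.975 ± 0.568 CPM in BMH21 (SD, n = 2 each; edgeR adjusted p = 0.0682, but called higher without BMH21 replicate 1, 1.84) and Prdm9 at 0.726 ± 0.150 and 0.524 ± 0.283 CPM (SD, n = 2 each; adjusted p = 0.618). Dmrtb1 was at 819 and 807 CPM and Syce1 at 423 and 420.4 CPM.

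Of 29 spermatid markers, 2 rose, Crisp2 (0.09) and Garin3 (0.60), and 1 fell, Izumo1 (-0.60); adjusted over the list alone 1 rose and 1 fell. Crisp2 lost its call under upper quartile scaling (0.05), Garin3 in DESeq2 (0.60), with the replicate number as a block (0.59) and without mock replicate 2 (0.50) or BMH21 replicate 2 (0.35), and Izumo1 without BMH21 replicate 2 (-0.37). Odf2 was at 1983 and 1986 CPM. Of 8 Sertoli cell, 6 macrophage and leukocyte, and 8 myoid, endothelial and red blood cell markers, 0 were called in edgeR, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 in DESeq2. Dhh was at 3.65 and 4.01 CPM, Amhr2 at 2.53 and 2.44, Aif1 at 8.78 and 9.30, H2-Ab1 at 7.23 and 7.80, Tagln at 4.41 and 5.31 and Vwf at 1.73 and 2.03 CPM. Of 2 Leydig cell markers, Star fell (-0.50), losing its call without BMH21 replicate 1 (-0.44), and Insl3 was at 0.236 and 0.465 CPM; 0 rose and 1 fell adjusted over the list alone, and edgeR at an unadjusted p under 0.05 and DESeq2 gave the same counts.

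Whether the counting used strand, and how it shared reads between overlapping genes, is not given in the sources used here, so the values of named genes that overlap another annotated gene are uncertain. Of the 176 named genes, 16 share exons with another gene on the same strand: Fmr1, Ell2, Emd, Rpl10, Hspa8, Ripk1, Dhh, Pdia4, Gnl3, Izumo1, mt-Nd2, mt-Nd4, Insl3, Rnf8, Spata22 and Snhg4. A further 33 overlap an antisense gene: Supt5, Msh4, Dnajb9, Top2b, Sycp3, Sptbn1, Id4, Rad17, Dnm1l, Cdkn1a, Sox8, Gfra1, Cdk2, Stag2, Hspd1, Mllt10, Odf2, Itga4, Casp9, Atf7ip, Tagln, Mybbp1a, Zfp36, Polr1a, Jun, Tdrd5, Ei24, Utp14a, mt-Co1, mt-Nd5, mt-Nd6, Uba1y and Zfx. Near-identical copies were found for Rpl10, Insl3, Rbmxl1, Snhg4, Spata22, Zfy1, Zfy2 and Gm21095.

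The authors' deposited table put 584 genes in its class up and 185 in its class down. Of the genes classed up in the authors' deposited table, 247 were X-linked, 10 Y-linked and 327 autosomal, and 1 X-linked gene was classed down. The classes of the authors' deposited table equalled an unadjusted p under 0.05 with a fold change over 2 for all 15733 genes, and 180 of the genes classed up or down in that table had an adjusted p of 0.05 or more. Of the 584 genes classed up in the authors' deposited table, 556 were also called higher by edgeR.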

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

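TMM factors from autosomal genes, DESeq2 on the filtered genes, the counts of calls per chromosome class and camera on autosomal genes alone were chosen after the results were seen. Across RLE size factors, upper quartile scaling, DESeq2 (on all listed genes, or on the filtered genes), no filter, a stricter filter and autosomal TMM factors, between 2956 and 4285 genes were called, against 4013. Leaving out 1 library, with the lone sample of its arm assumed to vary like the other group, gave 2997 to 3549 calls, 1805 to 2057 higher and 1180 to 1492 lower, and 3.92 to 4.07 for the X minus autosome difference. With the replicate number as a block 3784 genes were called, 2189 higher and 1595 lower; deviations of libraries of the same number correlated at 0.0105, so the numbers were not taken as pairs. A fold change of at least 2 left 712 genes, 561 higher and 151 lower, with 307 and 150 on the autosomes, and an adjusted p under 0.01 left 1133 lower genes, 1129 of them autosomal; both follow from the threshold itself. The stricter filter left 120 X-linked genes called higher because it tested 142. With an estimated correlation 0 gene lists were called, and the self-test also gave 0.

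Of 2079 log2 fold changes of 176 named genes under the alternatives, 120 of them from the rule, 1935 kept their direction and side of the threshold, 117 lost the call, 4 gained it and 23 changed sign. With 1 library left out 76 lost the call and 17 changed sign; DESeq2 lost 17 calls on all listed genes and 14 on the filtered ones. The call was gained by Dmrtb1 (-0.07 under upper quartile scaling), Utp14a (1.30 with RLE size factors and 1.30 without a filter) and Dmc1 (1.84 without BMH21 replicate 1). All that changed sign were genes without a call. Under upper quartile scaling Polr1a read -0.0224, Pgk2 -0.0193, Pdha2 -0.0239, Gm21095 -0.0333 and Odf2 -0.0437, and under the stricter filter Odf2 read -7.53e-04. With 1 library left out, values ran from -0.15 to 0.92 for Cdkn1a, -0.31 to 0.17 for Gfra1, -0.0353 to 0.0098 for Syce1, -0.00692 to 0.0136 for Odf2, -0.27 to 0.44 for Dhh, -0.156 to 0.0614 for Amhr2, -0.19 to 0.81 for Vwf, -0.52 to 1.47 for Flna, -1.15 to 0.0047 for Prdm9 and -0.39 to 0.34 for Gm21095. The cause was not tested. Restricting X to protein-coding genes moved nothing, since the table lists no others. The alternatives with other pseudocounts were not run because counts were given. With 0.5 CPM added before the log, the X minus autosome difference between single libraries was 2.21 to 2.34, against 4.19 in the main fit. Depth limits which genes could be tested: of 432 listed X-linked genes, 89 had too few counts to pass the filter.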

Other observations

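The test of other cell types, the test of earlier stages and the share of X-linked genes without a copy that were not called higher were chosen after the result was seen. The limits of the test of earlier stages were set with the values of its markers known, and it took the place of a test on genes close to 0 in mock, whose values stand with the X-linked results.

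Several X-linked genes have a Y-linked homolog, and both members rose in each of 5 pairs looked at after the values were seen, to unequal levels. In BMH21, Eif2s3x, a translation initiation factor gene, was at 0.569 CPM and Eif2s3y at 64.1 CPM. The helicase gene Ddx3x was at 22.2 CPM and Ddx3y at 13.4 CPM, and the deubiquitinase gene Usp9x at 275 CPM and Usp9y at 104 CPM. The histone demethylase gene Kdm6a was at 2.91 CPM and its homolog Uty at 6.60 CPM. Uba1, which encodes the ubiquitin-activating enzyme, rose by 0.71 on the log2 scale, from 5.16 to 8.43 CPM, and Uba1y by 4.03, from 0.813 to 13.4 CPM. The differences between the members of a pair were not tested. Without mock replicate 1 the log2 fold change went from 4.23 to 7.28 for Eif2s3x, from 6.28 to 10.80 for Uty and from 6.20 to 6.83 for Ddx3x, and without mock replicate 2 it was 3.49 for Eif2s3x and 5.49 for Uty; both were at 0 CPM in mock replicate 2.

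Transcripts of the X-linked genes that passed the filter rose by a median of 4.19 on the log2 scale. Reads shared between gene copies could raise many genes at once, but the 287 X-linked genes without a near-identical copy had a median of 4.17. Spermatogonia or somatic cells, which the Hoechst sort would largely remove, would bring their abundant transcripts, but 34 autosomal markers of them had a median of -0.04 (-0.0446; 1 higher, 3 lower) and a median level of 1.12 CPM in mock, with Id4 the most abundant at 35.2 CPM in BMH21; the 1 higher, the spermatogonial gene Sohlh2 (0.582 to 5.62 CPM, 3.28), went the way this explanation predicts. Cells from before the silencing of X would raise leptotene and zygotene markers. The 6 autosomal ones under 10 CPM in mock had a median of 0.11 (0.113; range -0.63 to 1.35, 0 called higher by edgeR and 1 higher at an unadjusted p under 0.05). Dmc1, at 1.35 with an upper 95% bound of 2.47, went the way this explanation predicts and read 1.84 without BMH21 replicate 1. The limit of 10 CPM left out Sycp1 (0.27), the 1 autosomal marker of this list that was called higher. With 6 weakly expressed genes kept by a limit set with their values known, this test is the least firm of the 3 and cannot decide. A weakening of sex chromosome silencing under BMH21 is a hypothesis that these data may be consistent with, found and tested on the same libraries; how it would follow from the compound was not tested.

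Of 343 X-linked genes, 92 were not called higher, with Akap4, itself on the spermatid marker list, the best expressed of those named. Too few counts could explain a missing call, but for 76 of the 92 (82.6%) the upper 95% bound of the log2 fold change was below 2, which argues against a missed rise of the size of the X-linked median there; smaller rises, and larger ones in the other 16, stay open. Near-identical protein-coding copies were present for 20.7% of these genes and 12.3% of those called higher (Fisher's exact test, two-sided p = 0.0582), so for the 19 with a copy shared reads cannot be told apart from other reasons for a missing call. Of the 287 X-linked genes without such a copy, 73 were not called higher either (25.4%, 95% exact binomial interval 20.5 to 30.9), which argues against these copies as the whole source. The median of these 73 was 0.36 against 5.06 for those called, a gap that follows from the call itself. Reads shared with pseudogenes or less similar copies were not searched for. No biological explanation was tested. The fixed list of single-copy X-linked genes was compared with all other genes, not with the remaining X-linked genes.

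Autosomal genes that at least doubled numbered 307, of which 74 had a mean under 1 CPM and 188 one of 1 to 10 CPM. Reads from X-linked copies might have been counted on autosomal genes, but 0 of 305 searched had a near-identical X-linked copy among protein-coding transcripts. Their median transcript GC content differed by -0.291 percentage points from expression-matched autosomal genes (50.6% against 50.9%, permutation p = 0.6 with 10000 resamples), which argues against a GC bias as the source. A response of these genes to the treatment stays open as a hypothesis, untested beyond the comparison itself.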
